A study of Homo sapiens with 6 samples.

How the data were processed

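The samples were RNA fractions of the Hodgkin lymphoma lines L1236 and L428: the Ago2 IP and the total lysate of both lines, and the flow-through of L1236. Each fraction was hybridised against total RNA of its own line on Agilent 2-colour arrays, with the dyes exchanged on the other array of each pair. Groups and dye orientation were taken from the sample titles and channel labels. The 6 arrays form 3 dye-swap pairs, and the arrays of a pair hold the same RNA extracts. The labels do not say whether the total RNA of L1236 was a single extract in its IP and FT pairs, so no correlation between the IP and FT ratios of L1236 is given.

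Scans were quantified with Agilent Feature Extraction 9.1, per the submitters' processing notes. The deposited scanner files give, per the file headers, spot intensity in the red (Cy5) and green (Cy3) channels, local background intensity, Agilent's processed intensity, flags, and a log10 ratio of red over green for each spot. The deposited value table of the series holds a log10 ratio of fraction over total: against the scanner files it differed from the authors' log10 ratio by at most 5e-06 once the arrays with the fraction in Cy3 were turned, and each column had a median of 0. Its scale, centring and direction are therefore settled. Other deposited columns used were the flags for spots well above background, saturated or outlying, which carry no unit per the file headers.

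Mean spot intensity was corrected with normexp and an offset of 50 against the median local background, and ratios were normalized by loess within each array, with weight 0 for the 1639 control spots and for outlier flags. All ratios were turned to fraction over total, spots of a probe were averaged, and outlier spots, 10 to 20 per array among 43376, were left out. A probe was kept when its fraction or total channel was well above background on both arrays of at least 1 pair, which held for 25459 of 41000 probes. A probe with several spots counted as above background when at least 0.5 of them were. Probes were named through their RefSeq accession for 23434 probes, through the array's symbol for 2317 and through an older symbol for 1043, using a RefSeq gene table (assembly GRCh38.p14) for names only. For 745 probes the array's own name was kept, and 13461 had no gene. The probe with the highest mean intensity stood for its gene, which gave 12797 genes. Of 4640 genes with several kept probes, 462 had probes that differed by over 2-fold in IP over T, and 7 had probes at least 2-fold apart from 0 in opposite directions.

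Pair means were fitted with limma 3.58.1 in R 4.3.3 with the data.table package, version 1.17.8, with a coefficient for IP, estimated from both lines, and a coefficient for FT. The fit had 1 residual degree of freedom and empirical Bayes moderation added 3.09 prior degrees of freedom. Each SE in the text comes from this moderated variance. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. "Rose" and "fell" refer to such calls. In the contrast of IP with FT, the lone FT pair is assumed to vary like the IP pairs. Counts of 2-fold genes need the ratio on every array of the pair and carry no test. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 23 lists, and each list's median was ranked among 10000 random lists matched on mean intensity in 20 bins. For a fraction that was not well above background on any IP array, a bound was computed from channel values after loess and Aquantile scaling, as the bright fraction's mean over the dim fraction's mean, where each array of the latter took the higher of its own value and the lowest value among probes well above background.

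The genes named in the text were chosen by a rule fixed before the data were examined. It takes the 15 highest and 15 lowest genes by the smallest ratio over the 4 IP arrays, among called genes with a symbol on the array and IP and T both well above background and unsaturated. Fewer called genes would have been filled up from the same order. It adds up to 5 bounds each way, 5 genes each way for FT, 8 each way for differences between lines, up to 2 highest and 2 lowest members of each list, and the gene of Ago2. Called members of lists are named beyond it, and the text leaves out some of the genes it picked. Alternatives fixed at the same time were median centring, no background subtraction, Agilent's processed signals, the deposited log ratios and value table, no filter or a strict filter on dim probes, the mean of all probes, each dye orientation alone, a trended and robust prior, arrays as observations, a 1.5-fold threshold and each line alone. Genes with discordant probes were left out as an alternative chosen after the data were seen. A search of 3' UTRs for microRNA seed matches was planned and not analysed here, because no transcript sequences were used.

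The steps from normalization to gene calls and list tests were tested on simulated arrays of 11739 genes before use. An intensity cut stood in for the filter on flags. The bounds, the differences between lines and the alternatives were not simulated. For the comparison of IP with T, 94.1% and 91.7% of genes changed by 3 and -3 log2 units were called, 54.2% and 33.3% of those changed by 2 and -2, and 0 of those changed by 1 or -1, with 9 of 11589 unchanged genes called. A simulated list of 19 genes shifted upwards gave p = 1.12e-18 with the preset correlation and p = 0.0661 with an estimated correlation in this design (camera). Its genes varied independently of each other, whereas the estimated correlation of the real miR-17 family list was 0.616.

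Signal was weaker on the L428 slide: the median signal over background of its channels was 19.5 to 63.1 units, against 92.6 to 139 for L1236, and 51.2% to 54.3% of probes were well above background, against 54.6% to 63.7%. No spot was saturated. Arrays of L1236 shared a slide and scan, and those of L428 another.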

Results

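RNA recovered with Ago2 was measured in L1236 and L428, established cell lines of Hodgkin lymphoma, a cancer whose tumour cells derive from B cells. Ago2 is the Argonaute protein that carries microRNAs to the mRNAs they pair with. RNA from the Ago2 immunoprecipitate (IP) was hybridised against RNA of the total lysate (T) of the same line. In L1236, RNA of the flow-through (FT), the lysate left after the IP, was also set against T. Each of the 3 comparisons was made on a pair of 2-colour arrays with the dyes exchanged, so 6 arrays gave 3 dye-swap pairs. Arrays of a pair held the same RNA extracts and were counted as 1 replicate, which left n = 2 lines for IP over T and n = 1 for FT over T. The lines are separate samples, but each was sampled once. P-values and SE rest on the spread between the lines, which limma moderated towards a spread shared by all genes. An SE is therefore not a gene's own spread: MMD had an SD between lines of 0.04 and an SE of 0.17, JARID2 1.63 and 0.59. Between 51.2% and 63.7% of the 41000 probes were well above background in the IP or FT channel, and between 53.4% and 60.4% in the T channel. Median signal over background was 92.6 to 139 units in the channels of the L1236 arrays and 19.5 to 63.1 units in those of the L428 arrays. The number of arrays limits the precision.

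The comparison of IP with T asked which transcripts were enriched in the Ago2 IP of both lines. The samples hold no IP with a control antibody, so the ratios cannot separate binding to Ago2 from other RNA carried into the IP. Genes with the highest ratios are given here singly, and no function they might share was tested. SOCS1, an inhibitor of JAK-STAT signalling, had a log2 IP over T of 3.76 ± 0.18 (SE, n = 2), a 13.6-fold enrichment. BTG2, an antiproliferative gene, stood at 3.45 ± 0.18, and TRIB1, a pseudokinase of the Tribbles family, at 3.39 ± 0.25. Cell cycle regulators among the leading genes were CDKN1B, which encodes the CDK inhibitor p27, at 3.13 ± 0.21, and E2F7, a repressive E2F factor, at 3.20 ± 0.30. The cytokine CCL1 reached 3.02 ± 0.17 and the TWEAK receptor TNFRSF12A 3.06 ± 0.23. The kinase SGK1 stood at 3.26 ± 0.35 and DNAJB9, a co-chaperone of the endoplasmic reticulum, at 3.04 ± 0.20. The actin-binding CFL2 was at 3.48 ± 0.19, BOD1 at 3.24 ± 0.25, FAM222B at 3.18 ± 0.27, NABP1 at 3.16 ± 0.17 and MMD at 3.05 ± 0.17. Adjusted p for these genes lay between 0.013 and 0.0412 (limma), and all 4 IP arrays were above 0 for each. Further probes went as low as 0.56 for TRIB1, 2.03 for CDKN1B, 2.15 for both BOD1 and NABP1, 2.32 for CFL2 and 3.20 for SOCS1. On the simulated arrays, false calls made up more than the nominal share of 0.05 of the calls. Of 12797 genes tested, 202 rose and 147 fell in IP at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 3835 genes. With median centring in place of loess 928 were higher and 204 lower, 82.0% against 57.9% of the calls. With no filter on dim probes limma called 0 of 18068 genes, the lowest adjusted p was 0.0954 and 4043 genes had an unadjusted p under 0.05. Without the 462 genes whose probes differed by over 2-fold, an alternative chosen after the data were seen, 41 rose and 53 fell. Only 44 of the genes that rose and 57 of those that fell were among the 462. Of the genes that stayed in, 158 and 90 had been called, so the rest of the drop was a loss of calls among them, although 3554 of the genes tested then had an unadjusted p under 0.05 against 3469 of the same genes before.

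Transcripts too dim for a ratio gave bounds. WASL, an activator of actin branching, was not well above background in T on any IP array and was at least 2.18-fold higher in IP (adjusted p = 0.199, limma), a bound that L1236 carried, with 3.92-fold against 1.22-fold in L428. The corresponding bounds were 1.97-fold for LEFTY1, 1.91-fold for the Hippo kinase LATS1, 1.74-fold for ARL15 and 1.69-fold for FRS2, and their adjusted p lay between 0.0819 and 0.179. In L428 alone these bounds were 1.65-fold for LEFTY1, 1.26-fold for LATS1 and 1.22-fold for both ARL15 and FRS2, and in L1236 alone 2.33-fold, 2.90-fold, 2.47-fold and 2.34-fold. In the other direction, T was brighter by at least 1.30-fold for SPMIP8, 1.27-fold for PCDHA8, 1.19-fold for FAM201A and 1.12-fold for both GPATCH2L and FLJ12547, with adjusted p of 0.201 to 0.545.

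**Figure D1:**
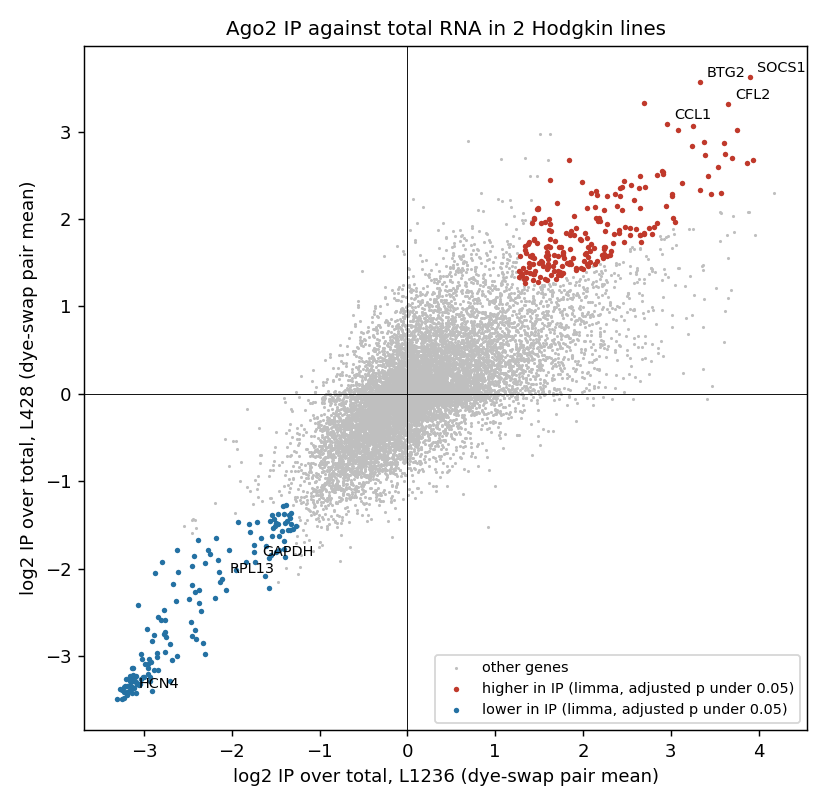
Each point is 1 of 12797 genes, with its log2 IP over T in L1236 on the horizontal axis and in L428 on the vertical axis, as means of the dye-swap pair. Red points are the 202 genes that rose and blue points the 147 that fell (limma, adjusted p under 0.05), and the values of the lines correlated across genes at r = 0.736.

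The 15 genes with the lowest IP over T under the naming rule lay close together, between -3.40 and -3.13. Each value is that of the gene's brightest probe. These probes may have read an RNA other than that of the named gene, a candidate explanation taken up in the last part. Log2 IP over T was -3.28 ± 0.18 (SE, n = 2) for the cardiac pacemaker channel HCN4 and -3.21 ± 0.17 for the NMDA receptor subunit GRIN2D. Genes of G protein-coupled receptors stood at -3.35 ± 0.18 (GPR153), -3.32 ± 0.17 (UTS2R) and -3.15 ± 0.18 (GALR3). Developmental transcription factors stood at -3.13 ± 0.18 (PHOX2A), -3.30 ± 0.18 (NPAS3), -3.26 ± 0.19 (DUX4) and -3.40 ± 0.17 (ZSCAN10). Also among the lowest were C18orf23 at -3.37, CDC42EP5 at -3.32, HS2ST1 at -3.32, PARD6G at -3.27 and KLF16 at -3.22. Adjusted p was 0.013 for all of these genes (limma), and all 4 IP arrays were below 0 for each. Their FT over T values were also alike, between 0.32 and 0.46. Of the 15, only 3 had further probes that passed the filter, and in all 3 these did not share the ratio: they reached 0.39 for HS2ST1, 0.06 for KLF16 and -0.06 for PARD6G. Of the 147 genes that fell, 132 lay outside the ribosomal protein, translation factor, housekeeping and histone lists, with a median log2 of -2.75 and a median intensity of 13.3 on the log2 scale. Further probes well above background existed for 43 of these genes, with a median of -0.16 where the brightest probes had -2.78. The 10 such genes within those lists had medians of -1.47 for further probes and -1.55 for the brightest.

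**Figure D2:**
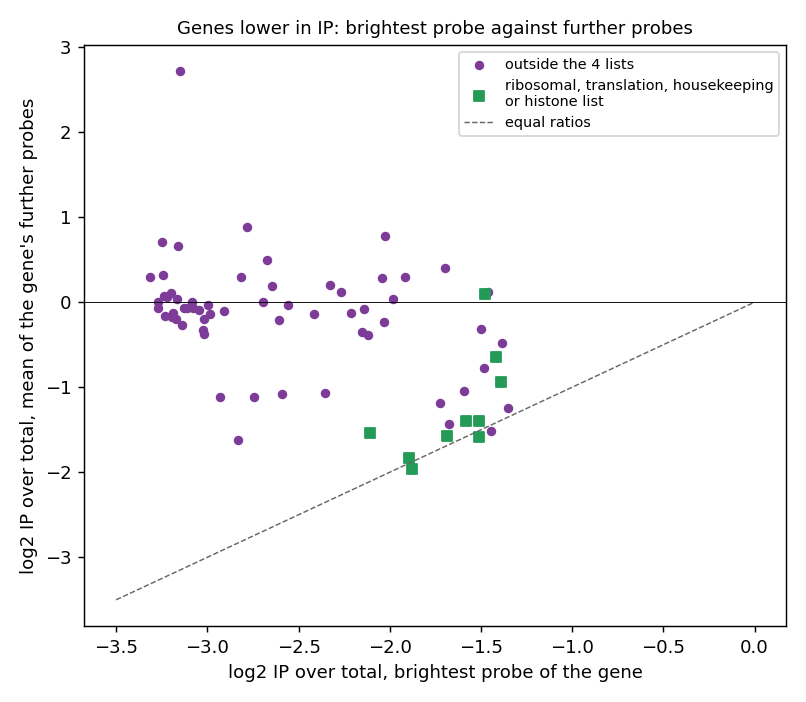
Each point is a gene that fell in IP and had more than 1 probe, with log2 IP over T of its brightest probe on the horizontal axis and the mean of its further probes on the vertical axis. Green squares, from the ribosomal, translation, housekeeping and histone lists, had a median of -1.47 on the vertical axis, and the dashed line marks equal ratios.

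Gene lists fixed before the data were examined were compared between IP and T with camera. All 5 lists of known microRNA targets were shifted towards IP at the preset correlation, and for each of them adjusted p = 0.75 with an estimated correlation. The 26 miR-155 targets had a median log2 of 0.87 (adjusted p = 0.000282), with 2 rising, SOCS1 and the signalling adaptor TAB2 at 1.84 ± 0.23 (SE, n = 2), and 12 passing when adjusted over the list alone. JARID2, a Polycomb cofactor, stood at 2.36 ± 0.59 and CSNK1A1, the lowest member, at -0.29 ± 0.25, with a further probe at 1.04. The 29 targets of the miR-17 family had a median of 0.67 (adjusted p = 0.000357), and 5 rose: ZFYVE26 at 2.83 ± 0.30, the cell cycle activator E2F3 at 2.36 ± 0.28, MYLIP at 2.24 ± 0.26, ZNFX1 at 2.20 ± 0.28 and the kinase gene YES1 at 2.17 ± 0.17. A further probe of ZFYVE26 stood at -0.11. With p adjusted over the list alone, 12 were higher and 1 lower. GPR137B had 2.89 ± 0.56 and MAPK9 -0.68 ± 0.17, and neither passed over all genes. The 25 let-7 targets had a median of 0.59 (adjusted p = 0.00197). DICER1, the enzyme that cuts microRNA precursors, rose at 2.31 ± 0.29, as did the RNA-binding IGF2BP3 at 2.09 ± 0.17 and the cytokine IL13 at 1.98 ± 0.24, and adjusted over the list alone 9 were higher and 1 lower. HRAS, the lowest let-7 target, had -0.91 ± 0.17. Of 19 miR-21 targets, median 0.74 (adjusted p = 5.21e-05), BTG2 rose and 9 passed adjusted over the list alone, while ACTA2 stood lowest at -0.24. Of 23 miR-15/16 targets, median 0.66 (adjusted p = 0.000482), the cyclin CCNE1 rose at 2.20 ± 0.18 and 6 passed adjusted over the list alone, with the mitotic kinase gene WEE1 at 1.90 ± 0.42 and CCND2 at -0.46 ± 0.23 not passing. The medians of these lists were lower in L428, at 0.32 to 0.45, than in L1236, at 0.87 or above, a difference that was not tested. For the mean of both lines, percentiles of the medians among 10000 random lists matched on intensity were 99.9 or above. In L428 alone they ran from 97.37 for let-7 targets to 99.75 for miR-21 targets.

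Immediate early genes and mRNAs with AU-rich elements, which turn over fast, had the highest median of the 23 lists, 1.07 over 31 genes (camera, adjusted p = 6.59e-08 with the preset and adjusted p = 0.75 with an estimated correlation). It was 1.32 in L1236 and 0.68 in L428. BTG2 rose, as did ZFP36, which encodes the AU-rich element-binding tristetraprolin, at 2.87 ± 0.33 (SE, n = 2), IER3 at 2.68 ± 0.19, the phosphatase gene DUSP2 at 2.34 ± 0.17 and ZFP36L1 at 1.43 ± 0.18, with a further probe at 0.38. There were 18 higher and none lower when adjusted over the list alone. GADD45A stood at -0.04 ± 0.18 and BTG1, the lowest, at -0.18 ± 0.18. Transcription factors with long 3' UTRs had a median of 0.64 over 41 genes (adjusted p = 0.000362, and adjusted p = 0.75 with an estimated correlation), with 1.00 in L1236 and 0.29 in L428. HIC2 at 2.23 ± 0.17, ZNF217 at 1.87 ± 0.19 and ZBTB34 at 1.59 ± 0.17 rose by their brightest probes, with further probes at -0.01 for HIC2 and 0.34 for ZBTB34, while ZBTB4 at 2.20 ± 0.55 and FOXK1 at -1.23 ± 0.23 did not pass, and 9 were higher and 1 lower when adjusted over the list alone. A further probe of FOXK1 stood at -0.11. TGF-beta and BMP signalling genes had a median of 0.44 over 32 genes (adjusted p = 0.00139, and adjusted p = 0.75 with an estimated correlation), with 0.90 in L1236 and 0.19 in L428. ZFYVE9, which anchors SMAD proteins at the receptor, rose at 2.24 ± 0.24, with a further probe at 1.21, while SKI at 1.66 ± 0.61 and the ligand TGFB1 at -0.65 ± 0.21 did not pass, and 5 passed adjusted over the list alone.

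**Figure D3:**
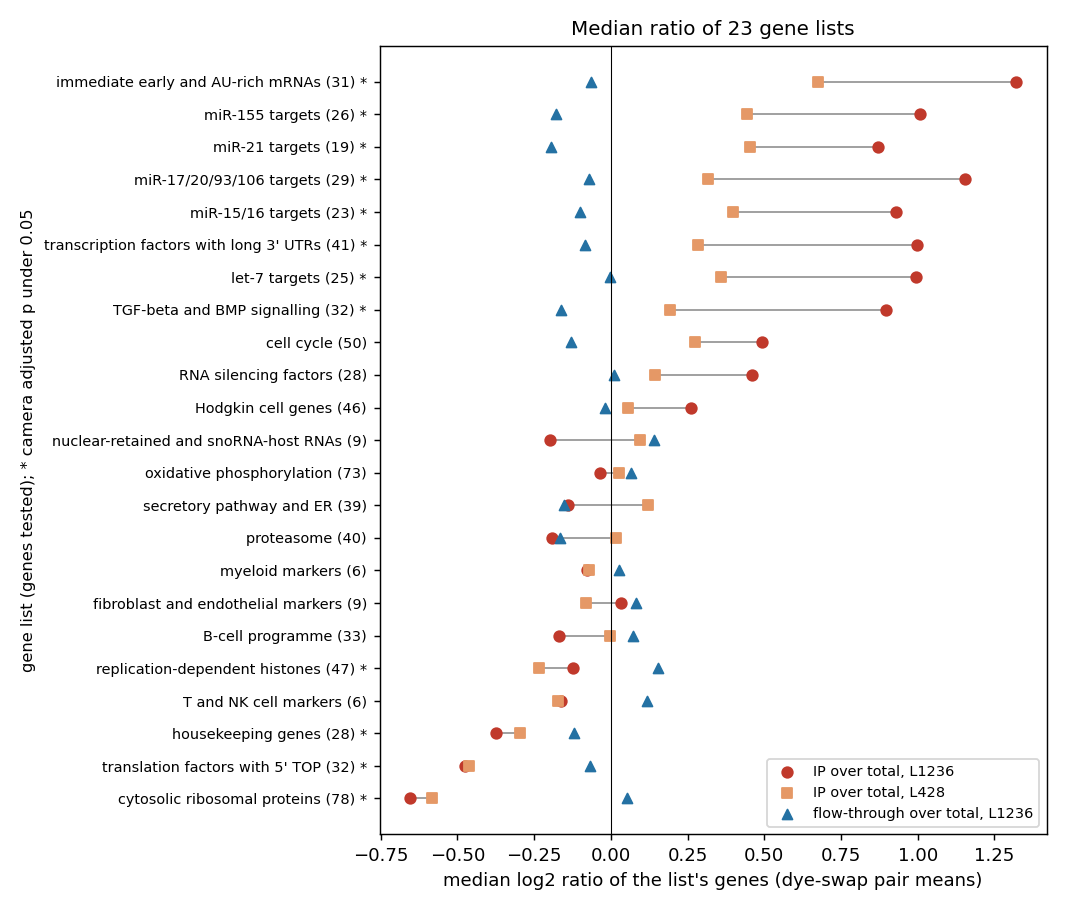
Median log2 ratio of each of 23 gene lists is on the horizontal axis, with circles for IP over T in L1236, squares for IP over T in L428 and triangles for FT over T in L1236. The list of immediate early and AU-rich mRNAs lay at 1.32 in L1236 and 0.68 in L428, and cytosolic ribosomal proteins at -0.65 and -0.58.

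Transcripts of the translation machinery, housekeeping genes and histones were shifted towards T at the preset correlation, and for each of these 4 lists adjusted p = 0.75 with an estimated correlation. Cytosolic ribosomal protein genes had a median log2 of -0.60 over 78 genes (camera, adjusted p = 6.59e-08), and 10 fell, including RPL13 at -2.11 ± 0.17 (SE, n = 2). RPS24 at 1.38 ± 0.18 and RPL36A at 1.38 ± 0.17 rose, and RPL22 stood highest at 1.99 ± 0.30 without passing. The highest RPL13 probe stood at -0.78 and the lowest RPL22 probe at 0.22. When adjusted over the list alone, 37 were lower and 6 higher, and no random list had a median as low (percentile 0 of 10000). Translation factors whose mRNAs start with a terminal oligopyrimidine tract had a median of -0.49 over 32 genes (adjusted p = 0.000482), with no member called. EEF1D at -1.44 ± 0.19 and TPT1 at -1.19 ± 0.29 were the lowest, NPM1 at 1.14 ± 0.17 and EIF3E at 0.91 ± 0.33 the highest, with further probes at -0.27 and -0.08, and adjusted over the list alone 3 were lower and 1 higher. Housekeeping genes had a median of -0.38 over 28 genes (adjusted p = 0.00561), and the glycolytic GAPDH at -1.83 ± 0.17 and ENO1 at -1.51 ± 0.17 fell, while TBP at 1.40 ± 0.18 and HPRT1 at 1.14 ± 0.18 lay above 0. Adjusted over the list alone, 10 were lower and 2 higher. That list did not pass with Agilent's processed signals (adjusted p = 0.0735, with 0.00155 to 0.0735 over all alternatives at the preset correlation). Replication-dependent histone genes had a median of -0.16 over 47 genes (adjusted p = 0.00818), and the histone H4 genes H4C3 at -1.46 ± 0.17, H4C13 at -1.41 ± 0.17 and H4C2 at -1.37 ± 0.17 fell, while H4C1 at 1.23 ± 0.36 and H3C1 at 1.00 ± 0.17 lay highest. Adjusted over the list alone, 6 were lower and 1 higher, and with only the arrays that held the fraction in Cy5 the list did not pass (adjusted p = 0.102, with 0.00099 to 0.102 over all alternatives at the preset correlation).

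The other 11 lists did not pass camera at the preset correlation. Of 28 RNA silencing factors, median 0.29 (adjusted p = 0.0694), DICER1 rose, and 4 passed adjusted over the list alone. The median of this list was 0.46 in L1236 and 0.14 in L428. The GW182 family genes TNRC6A at 2.82 ± 0.41 (SE, n = 2) and TNRC6C at 2.38 ± 0.37 did not pass over all genes, nor did SND1 at -0.68 ± 0.21 and DGCR8 at -0.58 ± 0.17, and a further probe of TNRC6A stood at 1.26. The gene of Ago2 itself had a log2 IP over T of 0.11 ± 0.29 (adjusted p = 0.837, limma), with 0.58 in L1236, -0.36 in L428 and 0.10 in FT. Of 50 cell cycle genes, median 0.38 (adjusted p = 0.069), CDKN1B, E2F3 and CCNE1 rose, while CDT1 at -1.19 ± 0.22 and TOP2A at -0.91 ± 0.17 were lowest, and 17 were higher and 3 lower when adjusted over the list alone. Genes known from Hodgkin cells numbered 46, with a median of 0.20 (adjusted p = 0.108), at 0.26 in L1236 and 0.05 in L428. Of these genes, SOCS1, IL13 and the apoptosis inhibitor BIRC3 at 1.67 ± 0.19 rose, and 6 passed adjusted over the list alone. The galectin LGALS1 at -1.20 ± 0.32 and the chemokine CCL5 at -0.69 ± 0.17 were the lowest of them. Among 73 oxidative phosphorylation genes, median 0.09 (adjusted p = 0.637), NDUFB11 fell at -1.44 ± 0.17, and adjusted over the list alone 4 were higher and 10 lower. Among 40 proteasome genes, median -0.05 (adjusted p = 0.0747), PSMB3 fell at -1.54 ± 0.18, the only member that passed adjusted over the list alone. Among 39 genes of the secretory pathway, median -0.03 (adjusted p = 0.673), SSR4 fell at -1.85 ± 0.20, and adjusted over the list alone 1 was higher and 4 lower. No gene passed among 9 nuclear-retained and snoRNA-host RNAs, median 0.13 (adjusted p = 0.876). For oxidative phosphorylation the test pointed down while the median lay above 0, and for the secretory pathway the mean was 0.03. Signs of the last 4 medians were not stable. With median centring the proteasome stood at 0.14 and the secretory pathway at 0.13, and with the fraction in Cy3 only oxidative phosphorylation stood at -0.02 and the nuclear RNAs at -0.06.

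Cell type markers were sparse. The B-cell programme, which Hodgkin cells have largely lost, had 33 tested genes with a median log2 of -0.10 (camera, adjusted p = 0.0847), none called. That median was -0.17 in L1236 and -0.003 in L428. BCL6 at 0.87 ± 0.25 (SE, n = 2) was among the highest, and HLA-DPB1 at -1.23 ± 0.17 and HLA-DMA at -0.96 ± 0.21 were the lowest. Only 6 of 26 T and NK cell markers could be tested (median -0.18, adjusted p = 0.159), from CD6 at 0.12 to CD4 at -0.68. Of 22 myeloid markers 6 were tested (median -0.09, adjusted p = 0.644), from CD14 at 0.63 to MARCO at -0.37. Of 22 fibroblast and endothelial markers 9 were tested (median -0.09, mean 0.02, adjusted p = 0.644), from FBN1 at 1.06 to THY1 at -1.16, and with no filter on dim probes that median was 0.01. Of the last list 1 gene was higher and 1 lower when adjusted over the list alone, and none of the other 3 lists had a call.

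The lines were compared for shared enrichment. A ratio of at least 2-fold on both arrays of a pair was found in IP for 1390 genes higher and 299 lower in L1236, and for 730 higher and 342 lower in L428. On all 4 IP arrays 442 genes were at least 2-fold higher, where independent lists of these sizes would share 79.3, and 182 were at least 2-fold lower, where they would share 7.99. Both lines were read with the same probes, so a probe that read another RNA would repeat in both. Neither these expected numbers nor the correlation below allows for that. For 43 of the genes that fell outside the 4 lists, further probes had a median of only -0.16. With median centring these counts were 259 and 114, and 649 genes were at least 2-fold higher in L1236. No gene was at least 2-fold higher in IP of L1236 and 2-fold lower in IP of L428, or the reverse. Across genes, which are not independent replicates, log2 IP over T of the lines correlated at r = 0.736 (rho = 0.689), against 0.928 and 0.888 between the dye-swapped arrays of L1236 and of L428. Each line lay on its own slide and scan, so line and slide cannot be told apart. The SD of log2 IP over T across genes was 0.805 in L1236 and 0.664 in L428, beside a technical SD from the dye swaps of 0.158 and 0.162.

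Flow-through RNA of L1236 was compared with T in the same way as the IP. Few genes differed from T there: APH1A, a gamma-secretase subunit, was the only gene at least 2-fold higher on both FT arrays, at a log2 FT over T of 1.55, and 19 genes were at least 2-fold lower. The lowest were BTG2 at -1.57, GAS1 at -1.39, the kinase MAPK6 at -1.35, the mitochondrial peroxidase PRDX3 at -1.31 and the zinc finger gene ZNF281 at -1.25. After APH1A, the highest by the weaker of the 2 arrays were TULP3 at 1.01, RNF19B at 0.93, the protease CTSZ at 0.91 and the calcineurin subunit PPP3R1 at 1.23. With the mean of all probes APH1A stood at 0.95, TULP3 at 0.45, PPP3R1 at 0.58 and MAPK6 at -0.97, and no gene was at least 2-fold higher on both FT arrays. The counts were 22 higher and 90 lower on the array with FT in Cy3 alone, and 6 and 67 with the deposited log ratios. BTG2 was 10.9-fold enriched in IP. Mean log2 IP over T of both lines was 1.14 for MAPK6 and 1.08 for ZNF281, but -0.24 for GAS1 and -0.88 for PRDX3. In L1236 alone it was -0.48 for GAS1 and -1.35 for PRDX3, so these genes were low in IP as well as in FT. Only 5 of the 442 genes at least 2-fold higher in IP of both lines were among the 19 lower in FT. The SD of log2 FT over T across genes was 0.24, with a technical SD of 0.168, and the arrays of the pair correlated at 0.349. The FT comparison has no replicate. On the simulated arrays the contrast of IP with FT called no gene, although some were changed by 3 or -3 log2 units in IP alone. A lack of calls in that contrast therefore does not show that IP and FT were alike. When IP of both lines was set against FT, limma called 0 genes higher and 0 lower, with 1917 genes at an unadjusted p under 0.05. Fits of the same form on pairs gave 26 higher and 52 lower with median centring, 365 and 162 with Agilent's processed signals, 224 and 149 with the deposited log ratios and 36 and 87 with the strict filter. The count was 723 higher and 333 lower when each array was an observation with the pair as a random block. Within the slide of L1236, which held IP and FT, the mean IP ratio exceeded the mean FT ratio by at least 2-fold for 1857 genes and lay as far below it for 534. For 1377 and 288 genes both IP arrays lay at least 2-fold above or below both FT arrays. A fit with slide as a block had no residual degrees of freedom. FT over T in L1236 and IP over T in L428, which share no RNA extract, correlated across genes at r = -0.352 (rho = -0.347).

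Differences between the lines had no test, since each line had a single pair. Both L1236 arrays exceeded both L428 arrays by at least 2-fold for 476 genes, and the reverse held for 79. Log2 IP over T was higher in L1236 for the transcription factor NFIB (3.37 against 0.29), for DET1 (3.60 against 0.59) and for the nuclear receptor coactivator NCOA3 (3.65 against 1.10). GIGYF1 (3.62 against 0.95), the chromatin organiser SATB1 (2.53 against 0.23), STX6 (2.91 against 0.43) and the exchange factor PREX1 (0.92 against -1.53) were also higher there. L428 was higher for BEX5 (2.14 against 0.17), the mitochondrial DNA-binding SSBP1 (1.95 against 0.11), EFCAB11 (1.88 against 0.35) and MOB4 (1.69 against -0.12). MGAT4A (1.64 against -0.05), RSL24D1 (1.58 against -0.27), DCPH1 (1.41 against -0.52) and PCNP (1.06 against -0.57) followed. Log2 FT over T in L1236 was also below 0 for DCPH1 (-1.08), PCNP (-1.06), MOB4 (-0.77) and RSL24D1 (-0.36), and lower there than in IP. A low ratio in L1236 was thus not particular to IP for these genes. For MGAT4A, BEX5, SSBP1 and EFCAB11, FT over T lay between -0.14 and 0.04. Further probes went as low as -0.20 for STX6, 0.78 for NFIB, 0.88 for GIGYF1 and 1.32 for NCOA3 in the mean of both lines, where their brightest probes stood at 1.67, 1.83, 2.28 and 2.37. The balance depended on the normalization: by pair means, 788 genes were at least 2-fold higher in L1236 and 229 in L428, and with median centring in place of loess 455 and 864. By all arrays, median centring gave 65 and 38.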

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

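All tests of explanations in this part were chosen after the results were seen.

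Several named genes had IP over T above 0 on both arrays of a line and below 0 on both arrays of the other, a difference that was not tested, since each line had a single pair. Log2 IP over T in L1236 minus that in L428 was 2.45 for PREX1, 1.23 for RNF19B and 0.94 for AGO2. It was -1.93 for DCPH1, -1.85 for RSL24D1, -1.81 for MOB4, -1.69 for MGAT4A and -1.63 for PCNP. All but RNF19B and AGO2 were picked for their large gaps between the lines, which favours opposite signs. Of all 12797 genes, 9526 had the same sign in both lines by pair means. MGAT4A at -0.05 and MOB4 at -0.12 in L1236 lay within the technical SD of 0.158. For DCPH1 and PCNP, FT over T in L1236 was below 0 too, at -1.08 and -1.06.

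Probes without a gene name were used in no comparison of the report. Of 6479 such probes that passed the filter, 97 (1.5%) were at least 2-fold higher and 219 (3.38%) at least 2-fold lower on all 4 IP arrays. Of 12797 named genes, each read by its brightest probe, 442 (3.45%) and 182 (1.42%) were. Why the lower probes prevailed among those without a name was not tested. On the arrays of L1236 alone 449 of the probes without a name were higher and 350 lower, and on those of L428 alone 166 and 265. On both FT arrays 1 was higher and 6 were lower.

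More genes were at least 2-fold higher in L1236 than in L428 (476 against 79). Weaker signal on the L428 slide, which would compress its ratios, is a candidate explanation: over the 3200 genes with the highest intensity the SD across genes in L1236 was 1.02 times that in L428, against 1.38 times over the other genes. A part played by loess stays open: with median centring 34.5% of the line differences by pair means were higher in L1236, against 77.5% with loess, but by all arrays 65 genes were still higher in L1236 and 38 in L428. Among the 3200 genes with the highest intensity, 197 were still higher in L1236 and 102 in L428 by pair means. A difference between the slides cannot be told apart from a difference between the lines, because 0 slides held arrays of both, and a biological difference of the lines stays open and untested.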

How the results depend on the processing

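The alternative without genes whose probes disagree was chosen after the data were seen, and the cause of each change below was not tested except where it is named. None of the 83 called genes that the rule picked or the text names, and none of the called gene lists, changed direction under any alternative run for them. Calls of IP against total (202 higher, 147 lower) were 928 higher with median centring, which raised the median of all genes in L428 to 0.14, and 204 lower. They were 1722 and 1232 with Agilent's processed signals, 1539 and 1237 with the deposited log ratios and also with the value table, and 0 and 0 with no filter (limma, 4043 genes at an unadjusted p under 0.05), where the prior had 1.46 degrees of freedom in place of 3.09. They were 905 and 488 with the strict filter, 464 and 244 with the fraction in Cy5 only, 518 and 227 with a trended and robust prior, 2316 and 1518 with arrays as observations, which counts technical arrays as replicates, and 41 and 53 without genes whose probes differ by over 2-fold. All 349 called genes were also called by the trended prior and with arrays as observations, 348 with median centring, 258 with the mean of all probes, 267 with Cy3 only and 339 with Cy5 only. IP against flow-through (0 and 0) gave 26 higher and 52 lower with median centring, 365 and 162 with processed signals, 224 and 149 with the log ratios and the value table, 36 and 87 with the strict filter and 723 and 333 with arrays as observations.

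Counts of 2-fold genes moved as follows. In L1236 IP, 649 were higher and 172 lower with median centring, 2439 and 1068 at a 1.5-fold threshold, and the lower count was 527 with processed signals, 632 with the log ratios and the value table and 574 with the fraction in Cy5 only. In L428 IP, 136 were lower with median centring, 1107 were higher and 742 lower with processed signals, 1108 and 738 with the log ratios and the value table, 1708 and 1118 at 1.5-fold, and 721 lower with Cy5 only. In FT, 3 were higher and 57 lower with processed signals, 6 and 67 with the log ratios and the value table, 2 and 41 with Cy5 only, 22 and 90 with Cy3 only, 7 and 212 at 1.5-fold, 9 lower with median centring and 0 higher with the mean of all probes. In both lines, 259 were higher and 114 lower with median centring, 1067 and 578 at 1.5-fold, 317 lower with processed signals, 349 with the log ratios and the value table, 311 with Cy5 only and 118 without genes whose probes differ by over 2-fold. Leaving out a line gave 730 to 1390 higher and 299 to 342 lower, since fewer arrays then had to pass.

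Genes at least 2-fold higher in L1236 numbered 65 with median centring, 990 with Cy5 only, 751 with Cy3 only and 1270 at 1.5-fold. Those higher in L428 numbered 38, 339, 254 and 479 under the same settings, 171 with processed signals and 235 with the log ratios and the value table. The correlation between lines was 0.709 with median centring, 0.746 with no background subtraction, 0.766 with the strict filter, 0.724 with the mean of all probes, 0.711 with Cy5 only and 0.727 with Cy3 only. Camera called 8 lists higher and 4 lower, and 0 and 0 with an estimated correlation, where the lowest unadjusted p of the 23 lists was 0.144. The housekeeping list had adjusted p of 0.0735, 0.0732 and 0.0732 with processed signals, log ratios and value table. The histone list had 0.102 with Cy5 only. Lists that passed under an alternative alone were the cell cycle (adjusted p 0.0166 to 0.11 over the alternatives at the preset correlation), RNA silencing (0.02 to 0.102), proteasome (0.0374 to 0.325), Hodgkin (0.0443 to 0.134) and B-cell lists (0.0443 to 0.121). All 83 called genes lost their call with no filter, at adjusted p of 0.0954 or above. With the mean of all probes 14 lost it, among them HS2ST1 at -0.61 (adjusted p = 0.104, lowest over its alternatives 5.19e-05), HIC2, ZBTB34, ZFP36L1, ZFYVE9, MYLIP, YES1 and ZNFX1. With Cy3 only 19 lost it, with Cy5 only 5 and with no background subtraction 1. Of the 103 other genes, up to 63 passed under an alternative, the most with processed signals. Each array already paired a fraction with T of its own line, and the labels tie no samples together across lines. The search for seed matches and its alternatives, and a fit with slide as a block, were not run. Signal over background limits L428 most, where 51.2% to 54.3% of probes were well above it.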

Other observations

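All tests in this part were chosen after the results were seen, and so were the genes and groups named here.

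Grouped by the letters with which their symbols begin, 119 sets of at least 12 genes were compared with camera. DUSP genes, mostly phosphatases of MAP kinases and other phosphoproteins, had a median log2 IP over T of 0.70 over 20 genes (adjusted p = 0.0307), with DUSP2 and DUSP6 rising at 2.34 ± 0.17 and 1.64 ± 0.17 (SE, n = 2). ARL genes, small GTPases of membrane traffic, had 0.66 over 22 genes (adjusted p = 0.0307), with ARL2 at 1.55 ± 0.19 and ARL3 at 1.61 ± 0.19 rising, although a further probe of ARL3 stood at 0.08. ZBTB zinc finger genes had 0.51 over 38 genes (adjusted p = 0.0307) and ALG genes, most of which act in N-glycan assembly, 0.60 over 13 genes (adjusted p = 0.0419). RPL and RPS were the only sets that passed in the other direction, at -0.67 and -0.27. All 6 sets had adjusted p = 1 with an estimated correlation, and their medians kept their sign with median centring.

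Further called genes are named singly, and their groups did not pass where they were tested. Of 30 MED genes, most of them subunits of the Mediator complex, 4 rose: MED19 at 2.64 ± 0.25 (SE, n = 2), MED21 at 2.39 ± 0.21, MED31 at 1.74 ± 0.20 and MED28 at 1.66 ± 0.17. The median of the set was 0.30 (camera, adjusted p = 0.437). Both chains of the interferon gamma receptor rose, IFNGR1 at 1.34 ± 0.17 and IFNGR2, which stood at 1.49 in L428. SPRED1, an inhibitor of the Ras pathway, rose at 2.47 ± 0.17, with a further probe at 0.36. Of 13 RGS genes, which limit G protein signalling, RGS1 and RGS2 rose at 2.26 ± 0.17 and 1.58 ± 0.17, while the set had a median of 0.07 (adjusted p = 0.747), with -0.21 in L1236 and 0.21 in L428. The chemokine receptor CXCR4 stood at 1.77 ± 0.22 and the adhesion molecule CD58 at 1.71 ± 0.17. Among chemokines the values went apart: CCL1 rose at 3.02 ± 0.17, while CCL5 stood at -0.69 ± 0.17 and CCL17 at -0.55 ± 0.18 without passing, and the 12 CCL genes as a set had adjusted p = 0.856.

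The genes that fell in IP outside the ribosomal, translation, housekeeping and histone lists had a median log2 IP over T of -2.75, and FT values with quartiles of 0.34 and 0.44. A candidate explanation is that their probes read an abundant RNA other than that of the named gene. The median of their further probes was -0.16 over 43 genes, of which 9 were at least 2-fold lower, while for genes that rose it was 0.92 over 63. The brightest probes of those 63 genes had a median of 1.83, and only 29 of the 63 had further probes at least 2-fold higher. Further probes of the genes that fell were dimmer, so real depletion at a transcript end that they miss stays open for single genes. The same explanation is argued against for the genes within those lists, whose further probes had a median of -1.47 over 10 genes. Intensity-dependent normalization is argued against as well, because with median centring the 132 genes outside the lists had a median of -2.58.

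Across all genes, FT ratios ran opposite to IP ratios, but not in every gene list. The miR-155 targets had medians of 0.87 in IP and -0.18 in FT, and ribosomal protein genes -0.60 and 0.05. Housekeeping genes lay below 0 in both, at -0.38 and -0.12, as did translation factors at -0.49 and -0.07. The let-7 targets, at 0.59 in IP, stood at -0.001 in FT. The genes at least 2-fold higher in the L428 IP had a median log2 FT over T of -0.16 in L1236, and 408 of the 730 were below 0 on both FT arrays against 80 above. Across lines, with no extract in common, r was -0.352. The probes of genes lower in IP are argued against as the whole cause, because without the 342 genes 2-fold lower in the L428 IP, r was -0.31 over 12455 genes. The median FT ratio of the 730 genes lay at percentile 0 of 10000 random lists matched on intensity. That of the 342 genes lower in the L428 IP was 0.21, at percentile 100. Both percentiles follow from the negative correlation already seen, so they cannot tell its possible causes apart. Removal of Ago2-bound mRNA from the flow-through remains a hypothesis, because FT was measured in L1236 alone and once.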
